A study of Mus musculus with 18 samples.

How the data were processed

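Hypothalamus RNA was profiled in 18 male C57BL/6JGpt mice, 6 in each of 3 groups. Per the labels' protocols, obese mice were switched to fat-rich food when 6 weeks old, kept on it for 16 weeks or longer, and given 2 oral gavage doses a day of either TN-783, an NLRP3 inhibitor, at 50 mg/kg or its vehicle. Chow-fed lean mice of the same sex, background and age were not dosed. A 14-day period of vehicle gavage preceded dosing, and the labels do not say whether the lean mice took part in it. Dosing lasted 29 days per the labels, while the deposited sample table gives 28 days. The labels call the 18 samples independent biological samples, so p-values refer to the spread between animals.

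Libraries were made with a 3' mRNA kit that primes on the poly(A) tail and adds unique molecular identifiers, with 18 PCR cycles, per the labels' protocols. The submitters' processing notes name STAR 2.7.9a, Salmon 1.10.1, edgeR 4.6.2, R 4.5.1 and the GRCm39 build, without roles or order. How reads with the same molecular identifier were collapsed, and which annotation was used, is not given in the sources used here. The authors deposited estimated counts for 56980 features, of which 19684 were 0 in every library. Of all values, 12.0% differed from the nearest whole number, with a tolerance of 0. The deposited library sizes equalled the sums of these counts. The deposited scaling factors, a ratio per library between 0.936 and 1.08, differed by at most 0.00109 from trimmed-mean (TMM) factors computed here on all features. The deposited log2 CPM values were recomputed from the counts and these factors and differed by at most 8.88e-15. The RNA integrity score per sample is as deposited by the authors. No coordinates are printed because the reference at hand is of another build than GRCm39, and gene symbols are those paired with the identifiers in the deposited gene table.

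Genes with near-identical copies, such as those of haemoglobin and ribosomal proteins, are uncertain because the counting could split reads between copies, and whether counting used strand is not given in the sources used here. Estimated counts were rounded to whole numbers. Features were kept by edgeR's filterByExpr with a minimum count of 10, which left 11835 genes. The 3 groups were fitted together with edgeR 4.0.16 (R 4.3.3), TMM scaling and the robust quasi-likelihood test, with 15 residual degrees of freedom and a common biological coefficient of variation of 0.169. Each pair of groups was compared with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD (n = 6).

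Before the data were examined, 45 gene lists (inflammatory pathways, neuropeptides, metabolism, stress responses and markers of cell types and neighbouring tissues) were fixed, and the 37 with at least 4 tested genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01. Estimated correlations and fry were alternatives. Means of 6 inflammatory and glial lists per library were compared by two-sided exact permutation over all 924 splits of 12 libraries. The genes named in the text follow a rule fixed at the same time. It takes 6 inflammasome genes (Nlrp3, Il1b, Il18, Casp1, Pycard, Gsdmd) and Agrp, Npy, Pomc, Cartpt, Gfap and Aif1 in every comparison. It adds up to 10 called genes per direction, or the 3 genes with the smallest p per direction where none was called. For each list that passed or has at least 2 called members, it takes up to 4 called members, or 2 members with the smallest p where none was called. It also takes up to 10 genes called in both vehicle versus lean and TN-783 versus vehicle, of which there were 0. Genes that only have a model name are counted and not named. Other genes are named with a remark that they were chosen after their values were seen. The design assumed whole counts, and the rounding of estimated counts replaced that assumption.

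Alternatives were DESeq2 1.42.0, other scaling factors and filters, the 2 compared groups alone, a replicate block, RNA integrity, 1 surrogate variable (sva 3.50.0), limma voom with sample weights, and leaving out each library. The mean of the ribosomal protein list as a covariate, and leaving out the 2 vehicle libraries with pituitary transcripts, were added after the data were seen. Means of the tested genes of each of 37 lists were related to the first principal component with 100000 permutations, also after the results were seen. The edgeR test was tried on data simulated from the fitted means and dispersions, 5 runs per comparison of 11835 genes. For TN-783 versus vehicle it recovered 3.60% of genes changed 1.25-fold, 32.4% of those changed 1.5-fold, 77.2% of those changed 2-fold and 94.8% of those changed 3-fold. Those simulated genes varied independently, without the shifts shared by many genes that the libraries show, so sensitivity in the real libraries can be lower. Camera called the 1 raised list in 5 of 5 runs per comparison, and it called 0, 0 and 2 other lists, which were not raised as lists, over the 5 runs of vehicle versus lean, TN-783 versus vehicle and TN-783 versus lean. Libraries of the same group differed by a chi-square of 2.34 to 15.5 per degree of freedom over genes with at least 20 counts, so none was a duplicate of another.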

Results

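The hypothalamus, the brain region that controls feeding and energy use, was sampled from lean mice, from diet-induced obese (DIO) mice given vehicle and from DIO mice given TN-783, an inhibitor of the inflammasome sensor NLRP3. Each group held 6 animals. Library totals were 2069960 to 3695650 counts in lean mice, 1699650 to 2761380 in DIO vehicle mice and 1993460 to 3589650 in TN-783 mice. RNA integrity scores were between 9.4 and 10.0 in lean, 9.5 and 9.9 in vehicle and 9.6 and 9.7 in TN-783 samples. The first principal component held 26.9% of the variance, and lean replicate 6 lay at -30.8 on it while the other lean libraries lay between 13.6 and 31.7. DIO vehicle replicates 2 and 4 held pituitary transcripts: prolactin (Prl) was at 1773 and 1273 CPM in them and at most 30.2 CPM in the other 16 libraries.

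Genes of the drug's pathway were near the detection limit. Nlrp3 had 5, 6 and 4 counts over the 6 libraries of the lean, vehicle and TN-783 groups. Il1b, which encodes a cytokine that the inflammasome activates, had 2, 8 and 6 counts. Casp1, the protease of the complex, had 11, 12 and 9 counts, its adaptor Pycard had 40, 22 and 39, and the pore-forming Gsdmd had 6, 3 and 5. These 5 genes did not pass the expression filter. With no filter, 0 of the 5 were called in the 3 comparisons (edgeR, adjusted p at least 0.600), with standard errors of 0.42 to 1.01 on the log2 scale. Il18, the other cytokine precursor, was at 26.9 ± 5.56 CPM (SD, n = 6) in lean, 34.4 ± 6.74 in vehicle and 32.2 ± 3.75 in TN-783 mice. Its log2 difference was 0.36 (SE 0.15, edgeR adjusted p = 0.389) for vehicle versus lean and -0.10 (SE 0.15, adjusted p = 1.00) for TN-783 versus vehicle, where it was -0.19 without vehicle replicate 5 and -0.03 without TN-783 replicate 6.

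The comparison of DIO vehicle with lean mice asked what obesity and its diet changed. Sgk1 (ENSMUSG00000019970), a kinase gene induced by glucocorticoids, rose from 26.2 ± 13.3 to 85.8 ± 14.6 CPM (SD, n = 6), a log2 change of 1.75 (SE 0.26, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0315), and lay above the lean median in 6 of 6 vehicle libraries. It was the only gene of 11835 to pass. At an unadjusted p under 0.05 there were 1287 genes, 630 higher and 657 lower, where 592 would be expected by chance. DESeq2 called 22 genes, 20 of them higher, among which Prl, Gh, Cga and Pomc were abundant in vehicle replicates 2 and 4 as pituitary transcripts. It also called Pmch (adjusted p = 0.00217) and Tsc22d3 (0.0105), named after their values were seen, and Hbb-bs (0.0257) and Nfkbia (0.0486), which edgeR did not call with all libraries and the expression filter. Because lean mice were not dosed, diet and dosing differ together in this comparison.

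**Figure D1:**
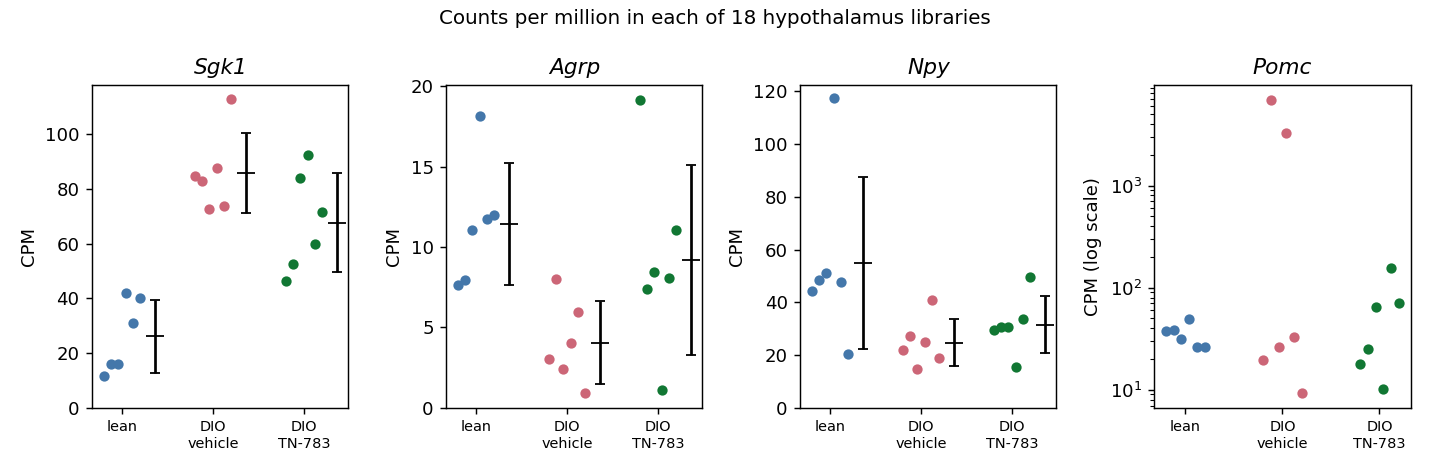
CPM of Sgk1, Agrp, Npy and Pomc (y axis, log scale for Pomc) in each library of the 3 groups (x axis); points are animals and black bars the mean ± SD of 6, which are left out for Pomc. Sgk1 was at least 46.2 CPM in the 12 DIO libraries and at most 42.0 CPM in the 6 lean ones, and Pomc reached 6939 and 3275 CPM in 2 vehicle libraries.

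The glucocorticoid-response list rose in camera with its preset correlation (adjusted p = 5.27e-08), with 10 of its 11 tested genes higher and a median log2 difference of 0.55; with an estimated correlation the adjusted p was 0.221. Over all genes 1 member passed, and adjusted over the list alone 5 did. Fkbp5 (0.84, SE 0.23) and Tsc22d3 (0.76, SE 0.17), both glucocorticoid targets, are named after their values were seen, and neither passed over all genes (adjusted p = 0.236 and 0.195). The blood list also rose by the preset test (adjusted p = 6.75e-05; 0.299 with an estimated correlation), with all 4 tested genes higher. Hbb-bs, a haemoglobin chain, differed by 1.47 (SE 0.36, adjusted p = 0.236) and Hba-a1 by 1.38 (SE 0.37, adjusted p = 0.269). Haemoglobin genes took 0.130% of counts in vehicle and 0.0554% in lean libraries (two-sided exact permutation p = 0.0260, 0.273 after Benjamini-Hochberg adjustment over 42 tests of library measures).

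The list of other hypothalamic neuropeptides fell by the preset test (adjusted p = 0.00352; 0.299 with an estimated correlation), with 8 of 11 genes lower and 0 past the threshold over all genes and 4 adjusted over the list alone. Oxt, which encodes oxytocin, differed by -0.94 (SE 0.29, adjusted p = 0.314), and Hdc, the histamine-synthesising enzyme, by -0.75 (SE 0.19, adjusted p = 0.207). The call was lost without the 2 vehicle libraries that held pituitary transcripts (adjusted p = 0.0570), a choice made after seeing the data, and with the mean of the ribosomal protein list as a covariate (0.204), another such choice. Receptors of feeding signals fell by the preset test (adjusted p = 0.0189; 0.397 with an estimated correlation), with 12 of 14 lower, among them Npy2r at -0.56 (SE 0.17) and the calcitonin receptor gene Calcr at -0.76 (SE 0.25). That call was lost without lean replicate 4 (0.0505), with RNA integrity as a covariate (0.133), with 1 surrogate variable (0.130) and with the ribosomal covariate (0.659). With all libraries and the expression filter, the appetite-promoting genes of the arcuate nucleus did not pass singly. Agrp was at 11.4 ± 3.81 CPM in lean and 4.06 ± 2.56 in vehicle mice, a log2 difference of -1.38 (SE 0.42, adjusted p = 0.301), with 6 of 6 vehicle libraries below the lean median. With no filter Agrp was called (-1.40, SE 0.27, adjusted p = 0.000993). The fold was similar there and the SE smaller, so that call came from a lower estimate of spread, whose cause was not tested. Npy differed by -1.13 (SE 0.34, adjusted p = 0.314), again with 6 of 6 below, and was called without lean replicate 6 (-1.28, SE 0.31, adjusted p = 0.0426). Their list was not called (adjusted p = 0.624), and its mean moved with the first principal component, as given below. How far Agrp and Npy singly follow that component was not tested. In the list Pmch, the melanin-concentrating hormone gene, which is named after its values were seen, was at a log2 difference of 0.66 (SE 0.13, adjusted p = 0.0879 over all genes, 0.000104 adjusted over the list alone). Cartpt differed by 0.11 (SE 0.12; 0.05 without lean replicate 6). Pomc, the precursor of the satiety peptide alpha-MSH, differed by 5.62 (SE 1.53, adjusted p = 0.274), and by -0.67 without the 2 vehicle libraries that held pituitary transcripts, another value of that same alternative.

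Of the 6 inflammatory and glial lists, 1 passed the preset test. The inflammasome list was tested on 6 genes, without Nlrp3, Il1b, Casp1, Pycard and Gsdmd, which failed the filter. The NF-kB and cytokine list rose (adjusted p = 0.0320; 0.221 with an estimated correlation), with 5 of 6 tested genes higher and 1 adjusted over the list alone; Nfkbia, which encodes an inhibitor of NF-kB, differed by 0.65 (SE 0.16, adjusted p = 0.207) and Vcam1 by 0.28 (SE 0.11). The call was lost without any one of vehicle replicates 4 (adjusted p = 0.0671) and 5 (0.0632) and lean replicates 1 (0.0573), 5 (0.0552) and 6 (0.0678), without the 2 vehicle libraries with pituitary transcripts (0.171), with at least 1 CPM in 6 libraries as the filter (0.0584), and with the ribosomal covariate (0.0691). Its mean per library was higher by 0.23 on the log2 scale (two-sided exact permutation p = 0.00866, 0.156 after adjustment over 18 tests), and by 0.19 without those 2 libraries (exact permutation p = 0.0333, 0.400 after adjustment over 12 tests). The inflammasome list (adjusted p = 0.509, with 0 genes past the threshold over all genes and 3 adjusted over the list alone, of which Nek7 at 0.50, SE 0.20, and Txnip at 1.18, SE 0.39, are named after their values were seen, and Il18 is the other), homeostatic microglia (0.813), disease-associated microglia (0.0664; called without vehicle replicate 3, 0.0350, or 6, 0.0209; 0.327 without the 2 libraries with pituitary transcripts), reactive astrocytes (0.848) and interferon response (0.757) were not called. Gfap differed by -0.20 (SE 0.20; -0.01 without lean replicate 6) and the microglial gene Aif1 by -0.01 (SE 0.35; -0.16 without lean replicate 5 and 0.45 without lean replicate 6).

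Lists of metabolism and of other cell types rose by the preset test and not with an estimated correlation. For ribosomal proteins 30 of 30 genes were higher (adjusted p = 5.27e-08; estimated 0.436), including Rps15 at 0.29 (SE 0.13) and Rpl5 at 0.43 (SE 0.21; 0.71 without lean replicate 6). For oxidative phosphorylation 29 of 30 were higher (3.04e-06; estimated 0.533), including Ndufb7 at 0.32 (SE 0.14) and Uqcr10 at 0.25 (SE 0.12). For fatty acid oxidation 12 of 13 were higher (0.000470; estimated 0.221), including Acadm at 0.33 (SE 0.11) and Etfdh at 0.71 (SE 0.26). Astrocyte identity genes (0.00352; estimated 0.436) were higher in 14 of 16, with Fgfr3 at 0.47 (SE 0.20) and Sox9, against the rest, at -0.25 (SE 0.10). Oligodendrocyte genes (0.00524; estimated 0.397) were higher in 13 of 16, with Aspa at 0.61 (SE 0.18) and the myelin gene Mobp at 0.47 (SE 0.17). Endothelial genes (0.00524; estimated 0.299) were higher in 11 of 15, with the glucose transporter gene Slc2a1 at 0.53 (SE 0.16) and Esam at 0.50 (SE 0.18). Mural cell genes (0.0334; estimated 0.299) were higher in 7 of 7, with Rgs5 at 0.30 (SE 0.11) and Vtn at 0.36 (SE 0.21). Heat shock genes fell (0.0330; estimated 0.299), with Hsph1 at -0.37 (SE 0.11) and Hsp90aa1 at -0.33 (SE 0.12). With the ribosomal covariate the calls of astrocyte identity (adjusted p = 0.145), oligodendrocyte (0.0815), mural (0.145), oxidative phosphorylation (0.729) and, by construction, ribosomal protein genes (0.923) were lost, and with RNA integrity as a covariate those of astrocyte identity and mural genes (0.0586 each). With 1 surrogate variable the astrocyte identity (0.150) and mural (0.0868) calls were lost. The endothelial call was lost without lean replicate 6 (0.125). The mural call was lost without vehicle replicate 1 (0.135) or 2 (0.133) or lean replicate 1 (0.0573), 4 (0.0517) or 6 (0.0889) or the 2 vehicle libraries with pituitary transcripts (0.0988), and that of heat shock genes without vehicle replicate 1 (0.0606) or 5 (0.0986) or lean replicate 4 (0.0517), 5 (0.109) or 6 (0.126). In all, 13 of 37 lists passed the preset test, 0 passed with an estimated correlation and 3 passed fry: glucocorticoid response, fatty acid oxidation, and NF-kB and cytokine genes. Other lists passed the preset test only under alternatives. Fibroblast genes (adjusted p = 0.0664) were called as lower without vehicle replicate 2 (0.0121) or 4 (0.0186) or these 2 together (0.000527), with the replicate block (0.0387) and with the ribosomal covariate (0.0263). Fatty acid synthesis genes (0.0759) were called as higher without vehicle replicate 4 (0.0314) or these 2 together (0.0212). General neuron genes (0.0833) were called as lower without vehicle replicate 5 (0.0257) or 6 (0.0218) or lean replicate 6 (0.0164), and ependymal genes (0.336) with the ribosomal covariate (0.0171).

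Several of these lists moved with the first principal component, which followed RNA integrity over 18 libraries at r = -0.721 (permutation p = 0.000600, 0.00180 after Benjamini-Hochberg adjustment over 3 relations) and rho = -0.709 (permutation p = 0.00123), at -0.568 without the 2 libraries farthest in integrity and at -0.711 over deviations from group means. Within lean, vehicle and TN-783 libraries r was -0.709, -0.870 and -0.586. For the other 2 measures r was 0.306 for total counts (permutation p = 0.224, 0.336 adjusted; rho 0.373, permutation p = 0.130; 0.288 without 2; 0.248 within groups; 0.186, 0.113 and 0.480 in lean, vehicle and TN-783) and -0.0491 for the mitochondrial percentage (permutation p = 0.848, 0.848 adjusted; rho -0.0547, permutation p = 0.830; 0.0106 without 2; 0.164 within groups; 0.0394, 0.823 and -0.0217 in lean, vehicle and TN-783). The relations of 37 lists to the component were computed after the results were seen, and the genes of a list also enter the component. Oxidative phosphorylation genes had r = -0.973 (rho -0.957, -0.966 without the 2 farthest libraries, -0.968 within groups), ribosomal protein genes -0.930 (rho -0.926, -0.930, -0.915), astrocyte identity genes -0.850 (rho -0.845, -0.835, -0.815), fatty acid synthesis genes -0.830 (rho -0.889, -0.848, -0.802) and oligodendrocyte genes -0.820 (rho -0.806, -0.758, -0.777). Other neuropeptides had r = 0.881 (rho 0.858, 0.890 without 2, 0.861 within groups) and feeding receptors 0.859 (rho 0.835, 0.806, 0.867). For these 7 lists the permutation p of r was at most 3e-05 (at most 0.000159 adjusted) and that of rho at most 0.000180 (at most 0.000832 adjusted); the smallest that the permutations can give is 1e-05. Fatty acid oxidation genes had r = -0.636 (permutation p = 0.00523, 0.0161 adjusted; rho -0.620, permutation p = 0.00693, 0.0197 adjusted; -0.640 without 2; -0.607 within groups; -0.693, -0.425 and -0.749 in lean, vehicle and TN-783) and mural genes -0.597 (permutation p = 0.00880, 0.0233 adjusted; rho -0.682, permutation p = 0.00252, 0.00848 adjusted; -0.744 without 2; -0.513 within groups; -0.810, -0.328 and -0.711). For blood, NF-kB, endothelial, heat shock and fibroblast genes r lay between -0.456 and 0.336 (permutation p at least 0.0578, at least 0.119 adjusted; rho -0.385 to 0.358, permutation p at least 0.117, at least 0.217 adjusted; -0.636 to 0.489 without 2; -0.328 to 0.171 within groups; -0.882 to 0.747 in single groups). For the glucocorticoid list r was -0.403 (permutation p = 0.0975, 0.164 adjusted; rho -0.416, permutation p = 0.0858, 0.167 adjusted; -0.439 without 2; -0.178 over deviations from group means), and within lean, vehicle and TN-783 libraries it was 0.0840, -0.847 and -0.260. Within each group the 5 lists with r of -0.820 or lower had r between -0.998 and -0.575 and other neuropeptides and feeding receptors between 0.776 and 0.978. Appetite-promoting neuropeptide genes, the list of Agrp and Npy, had r = 0.770 (permutation p = 0.000240, 0.000987 adjusted; rho 0.767, permutation p = 0.000390, 0.00160 adjusted; 0.745 without 2; 0.737 within groups; 0.844, 0.677 and 0.740 in lean, vehicle and TN-783).

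The count of called genes rested on single libraries. It was 346 genes, 196 higher and 150 lower, without lean replicate 6, 6 without vehicle replicate 5, 3 without lean replicate 5, and 2 without vehicle replicate 3 or lean replicate 4. It was 0 without any one of vehicle replicates 1, 2, 4 and 6, TN-783 replicates 5 and 6, and lean replicates 2 and 3. Sgk1 kept a log2 difference of 1.60 to 1.95 when each of the 18 libraries was left out. Of genes named above as not passing, Pmch, Tsc22d3, Fkbp5, Npy, Hdc, Calcr, Aspa, Mobp, Slc2a1, Rpl5, Hsph1 and Nek7 were called without lean replicate 6 (adjusted p between 0.0167 for Pmch and 0.0496 for Hsph1). Hbb-bs (0.0116) and Hba-a1 (0.00481) were called without vehicle replicate 5, Pmch without vehicle replicate 3 (0.0309) and Tsc22d3 without lean replicate 5 (0.0243). With no expression filter, where 37272 features entered the fit, Agrp, Hdc, Calcr, Pmch, Nfkbia, Tsc22d3, Fkbp5, Slc2a1, Mobp and Nek7 were called (between 3.62e-06 for Tsc22d3 and 0.0374 for Nek7). The estimates of spread changed in that fit, as seen for Agrp above, so these calls are not independent evidence. With limma voom and sample weights Pmch, Tsc22d3, Mobp, Slc2a1, Hdc, Aspa, Rpl5, Nek7 and Nfkbia were called (between 0.0182 for Pmch and 0.0489 for Nfkbia).

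**Figure D2:**
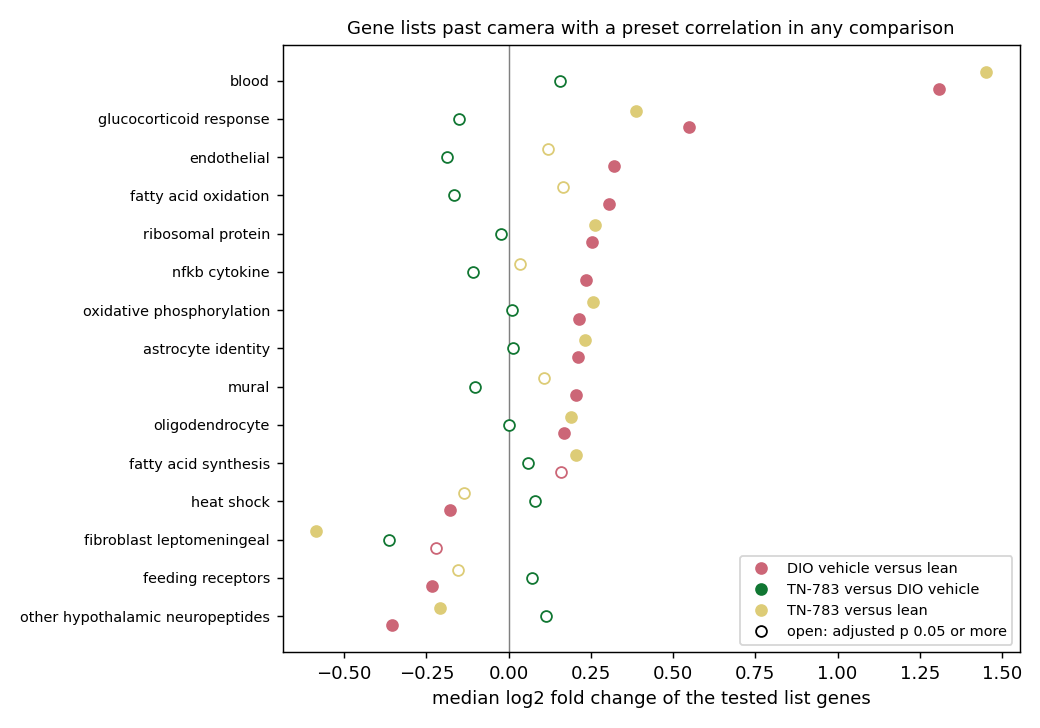
Median log2 fold change (x axis) of the tested genes of each list (y axis) that passed camera's preset test in at least 1 comparison. Filled points passed that test at 0.05 and open ones did not; 13, 0 and 9 lists passed for vehicle versus lean, TN-783 versus vehicle and TN-783 versus lean, and none of them passed with an estimated correlation.

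The comparison of TN-783 with vehicle asked what the drug changed in obese mice. No gene passed among 11835 (edgeR, smallest adjusted p = 1.00), 309 genes had an unadjusted p under 0.05, fewer than the 592 expected by chance, and DESeq2 called 0. Agrp was at 9.20 ± 5.90 CPM (SD, n = 6) with TN-783 against 4.06 ± 2.56 with vehicle, a log2 difference of 1.11 (SE 0.43, adjusted p = 1.00). Npy differed by 0.36 (SE 0.36), Cartpt by 0.09 (SE 0.12), Gfap by 0.04 (SE 0.20) and Aif1 by 0.33 (SE 0.34). Leaving out 1 library moved Npy to 0.16 (without TN-783 replicate 6) or 0.56 (vehicle replicate 5), Cartpt to 0.03 (TN-783 replicate 5) or 0.17 (TN-783 replicate 4), Gfap to -0.05 (vehicle replicate 1) or 0.13 (vehicle replicate 4) and Aif1 to 0.20 (TN-783 replicate 5). Pomc differed by -4.88 (SE 1.47, adjusted p = 1.00), and by 1.41 without the 2 vehicle libraries that held pituitary transcripts. The smallest p values of higher genes belonged to Mier2 (0.56, SE 0.13), Bean1 (0.75, SE 0.21) and the proteasome ubiquitin receptor gene Adrm1 (0.70, SE 0.21). Those of lower genes belonged to the histone methyltransferase gene Dot1l (-0.50, SE 0.14), D16Ertd472e (-0.42, SE 0.12) and the matrix protein gene Ccn2 (-1.33, SE 0.40; -0.88 without vehicle replicate 2).

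With all 18 libraries, TMM scaling and no covariate, no list passed with TN-783 against vehicle. The smallest adjusted p in camera was 0.585 with an estimated correlation. The list calls below under other fits are of the preset test. In the preset test on all 18 libraries the smallest adjusted p was 0.0510. It belonged to endothelial genes, lower in 14 of 15, to fatty acid oxidation genes, lower in 11 of 13, and to oligodendrocyte precursor genes, higher in 7 of 9. With RLE scaling these 3 lists were called (0.0494 each), and with RNA integrity as a covariate oxidative phosphorylation genes were called as higher (0.0126, against 0.741 without it). NF-kB and cytokine genes were not called (adjusted p = 0.270), and their mean per library was lower by 0.13 (difference -0.13, two-sided exact permutation p = 0.0216, 0.195 after adjustment over 18 tests), a difference that was -0.09 without the 2 vehicle libraries that held pituitary transcripts (exact permutation p = 0.152, 0.429 after adjustment over 12 tests). Disease-associated microglia genes were not called (adjusted p = 0.0841; called as lower without TN-783 replicate 1, 0.0326, or 4, 0.0262; 0.307 without the 2 libraries with pituitary transcripts), with a mean difference of -0.19 (exact permutation p = 0.0584, 0.351 adjusted), and of -0.09 without the same 2 libraries (exact permutation p = 0.262, 0.449 adjusted). The inflammasome list had a mean difference of -0.003 over its 6 tested genes (exact permutation p = 0.981). These leave out Nlrp3, Il1b, Casp1, Pycard and Gsdmd, so the value is no readout of them. Without the 2 vehicle libraries that held pituitary transcripts, antigen presentation (adjusted p = 0.00163, against 0.741 with them) and blood genes (0.000176, against 0.138) were called as higher. Endothelial genes were called without TN-783 replicate 4 (0.00245), vehicle replicate 4 (0.0337) or 5 (0.01003) or lean replicate 4 (0.0492) or 5 (0.0471). Fatty acid oxidation genes were called without TN-783 replicate 1 (0.0326) or 4 (0.00245), vehicle replicate 5 (0.0186) or lean replicate 4 (0.0492) or 5 (0.0471). Oligodendrocyte precursor genes were called without TN-783 replicate 1 (0.0326) or 2 (0.0109), vehicle replicate 6 (0.0421) or lean replicate 4 (0.0492) or 5 (0.0471). Blood genes were called as higher without vehicle replicate 4 (0.0197), feeding receptors as higher without TN-783 replicate 4 (0.0268) and ribosomal protein genes as lower without TN-783 replicate 1 (0.0326). Leaving out 1 library gave 4 called lists without TN-783 replicate 1 or 4, 3 without lean replicate 4 or 5, 2 without vehicle replicate 4 or 5, and 1 without TN-783 replicate 2 or vehicle replicate 6.

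Whether TN-783 moved diet-changed genes back was tested on the same libraries. The 1 gene called with diet, Sgk1, differed by -0.35 (SE 0.24, adjusted p = 1.00) with TN-783, an estimate toward the lean level that did not pass the test, so 0 of 1 called genes was called as moved back. Among the 200 genes with the smallest p for diet, 91.0% had the opposite sign with TN-783. Both comparisons use the same vehicle libraries, and unchanged groups simulated on them gave 93.7% (92.0% to 95.5% over 20 simulations). With the vehicle libraries split, 3 against lean and the other 3 against TN-783, the median over 20 ordered splits was 52.8% (19.5% to 68.0%). The labels were permuted on another computation of that share, from log2 CPM rather than edgeR, which gave 51.2% with the real labels and a median of 47.2% over 99 permutations (highest 85.8%, one-sided permutation p = 0.440). The log2 fold changes of the 2 comparisons correlated across genes, which are not independent replicates, at r = -0.56 against -0.52 simulated (-0.55 to -0.49 over 20 simulations), and at a median of -0.007 over the splits. Their covariance was -0.0345 against -0.0266 simulated (-0.0300 to -0.0245), a difference of -0.00791. Both observed values lay beyond the 20 simulations on the side of opposite change, unlike the share. The simulated genes varied independently, without the shifts shared by many genes in the libraries, so the simulated ranges can be too narrow. No reversal is concluded from these 2 values. Over the splits, the median covariance was -0.000641 (-0.0229 to 0.0320). In simulated data of 11835 genes, where 200 changed 2-fold with diet and 80% of that change was restored, the share with separate vehicle libraries was 89.0% of the 200 ranked genes, the mean of 2 runs. These genes also varied independently, and smaller diet changes were not simulated. The share that a weaker reversal would give is therefore not known, and the splits cannot exclude one.

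**Figure D3:**
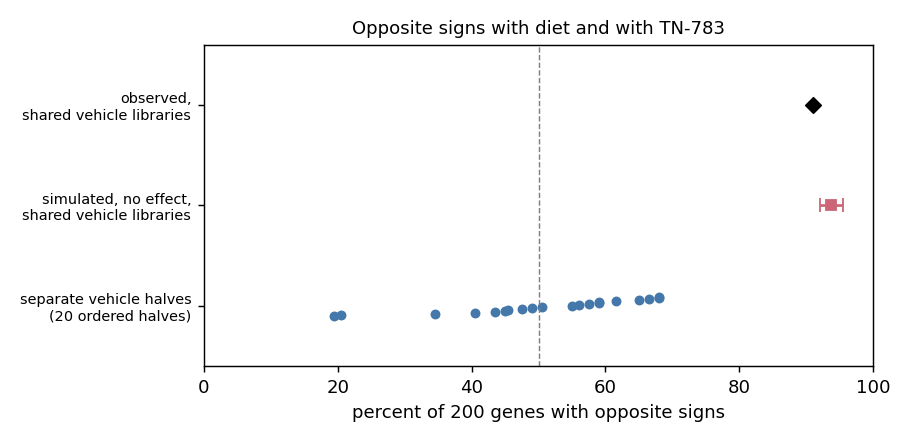
Percent of the 200 top diet genes whose log2 fold change had the opposite sign with TN-783 (x axis): observed (diamond, 91.0%), simulated unchanged groups that share the vehicle libraries (square, mean with lowest and highest of 20), and each of 20 ordered splits into separate vehicle libraries (circles). The dashed line marks equal signs and opposite signs in equal number; the circles scatter around it and the observed value lies below the simulated range.

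The comparison of TN-783 with lean mice asked how far treated obese mice differed from lean ones. No gene passed (edgeR, smallest adjusted p = 0.190), 966 had an unadjusted p under 0.05 and DESeq2 called 10. Among higher genes the smallest p values belonged to Cables1 (0.80, SE 0.15, adjusted p = 0.190), Sgk1 (1.41, SE 0.27, adjusted p = 0.190) and the early growth response gene Egr1 (0.62, SE 0.14), each above the lean median in 6 of 6 libraries. DESeq2 called these 3 (adjusted p = 0.00322, 0.000236 and 0.0420) and Hba-a1 (0.00797), Hbb-bs (0.0261) and Tsc22d3 (0.0371). With no expression filter Cables1 (1.17e-06), Tsc22d3 (9.35e-06), Col1a1 (0.000868), Egr1 (0.0116) and Dync2h1 (0.0343) were called, and with only the 2 groups Hba-a1 (0.000644), Hbb-bs (0.00174) and Cables1 (0.0163). Sgk1 and Cables1 were called with RNA integrity as a covariate (0.0386 each), Sgk1 with the replicate block (0.0176), and Sgk1, Cables1 and Egr1 with voom (0.0108, 0.0360 and 0.0439). Cables1 was called without vehicle replicate 5 (0.0328) or lean replicate 5 (0.0325), and Hba-a1 and Hbb-bs without vehicle replicate 5 (0.00118 and 0.0201). Col1a1, a collagen chain, differed by -1.50 (SE 0.31, adjusted p = 0.190), Slc26a2 by -0.76 (SE 0.18) and Dync2h1 by -0.55 (SE 0.13). Agrp differed by -0.26 (SE 0.37), Npy by -0.77 (SE 0.33), Pomc by 0.73 (SE 1.39), Cartpt by 0.20 (SE 0.12), Il18 by 0.26 (SE 0.15), Gfap by -0.17 (SE 0.19) and Aif1 by 0.33 (SE 0.33). Leaving out 1 library moved Agrp to -0.57 (without TN-783 replicate 1) or -0.06 (TN-783 replicate 4), Npy to -0.41 (lean replicate 4), Pomc to 0.14 (TN-783 replicate 5), Gfap to -0.26 (lean replicate 2) or 0.03 (lean replicate 6) and Aif1 to 0.18 (lean replicate 5) or 0.78 (lean replicate 6).

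Of 37 lists, 9 passed the preset test, 0 with an estimated correlation (smallest adjusted p = 0.266) and 0 by fry. Blood genes rose (adjusted p = 4.97e-08; 0.266 with an estimated correlation), with Hba-a1 at 1.70 (SE 0.37) and Hbb-bs at 1.55 (SE 0.36), and haemoglobin genes took 0.146% of counts (two-sided exact permutation p = 0.00216 against lean, 0.0909 adjusted). Glucocorticoid-response genes rose (adjusted p = 4.65e-07; 0.390 with an estimated correlation), with 11 of 11 higher and Tsc22d3 at 0.72 (SE 0.17). Oxidative phosphorylation genes rose (adjusted p = 4.97e-08; 0.575 with an estimated correlation), with 30 of 30 higher, among them Atp5j2 at 0.33 (SE 0.13) and Uqcrq at 0.36 (SE 0.15). Ribosomal protein genes rose (8.23e-08; estimated 0.575), with 30 of 30 higher, among them Rpl18 at 0.45 (SE 0.22) and Rpl4 at 0.23 (SE 0.13; 0.40 without lean replicate 6). Astrocyte identity genes rose (0.000449; estimated 0.528), with Gjb6 at 0.26 (SE 0.10) and Sox9, against the rest, at -0.29 (SE 0.10). Oligodendrocyte genes rose (0.00120; estimated 0.521), with Aspa at 0.50 (SE 0.18) and Fa2h at 0.50 (SE 0.23). Fatty acid synthesis genes rose (0.0115; estimated 0.521), with Srebf1, a regulator of that pathway, at 0.48 (SE 0.18) and the desaturase gene Fads2 at 0.29 (SE 0.13). Fibroblast genes fell (0.00599; estimated 0.488), with Col1a2 at -0.59 (SE 0.21), and so did other neuropeptides (0.00599; estimated 0.521), with Oxt at -0.91 (SE 0.29) and Hdc at -0.53 (SE 0.18). With the ribosomal covariate the calls of oxidative phosphorylation (adjusted p = 0.612), other neuropeptides (0.307), fatty acid synthesis (0.0511) and, by construction, ribosomal protein genes (0.967) were lost. The fibroblast call was lost without lean replicate 6 (adjusted p = 0.131) and that of fatty acid synthesis without TN-783 replicate 4 (0.0585). Ependymal genes were called as lower with the ribosomal covariate (0.00609) or without lean replicate 4 (0.0460), feeding receptors as lower without lean replicate 6 (0.0371), heat shock genes as lower without lean replicate 1 (0.0303) and antigen presentation genes as higher with 1 surrogate variable (0.0153). The gene count was 5 without vehicle replicate 5 and 1 without TN-783 replicate 3 or lean replicate 5.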

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

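The tests of a change in the vehicle group as a whole, of a mislabelled library, of the covariate with lean replicate 6 left out, and of the differences of the 346 genes with the covariate were chosen after the results were seen, as was each fit without the 2 pituitary-bearing libraries or with the ribosomal covariate. A gap test at Dixon's 95% value for 6 samples (0.625) marked 23 of 201 groups of values, where chance gives 10.05, and 8 of the 23 were lean replicate 6.

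That library lay at -30.8 on the first principal component, against 13.6 for the nearest lean library. Its log2 CPM was 4.04 for the oligodendrocyte gene Aspa, 8.37 for the ATP synthase gene Atp5j2, 7.29 for the astrocyte gene Gfap, 5.28 for Il18, 8.30 for Rpl4 and 10.00 for Rpl5, each above the other lean libraries, whose nearest values were 3.49, 7.79, 6.49, 4.75, 7.64 and 8.98. Its calcitonin receptor gene Calcr was at 3.49 against 4.43 for the nearest lean library. In lean replicate 4, Srebf1 was at 3.37 against 4.24.

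Among vehicle libraries, replicate 4 had the lowest Bean1 (2.14 against 3.29), Cartpt (5.84 against 6.15) and homeostatic microglia mean (3.74 against 4.01). Replicate 2 had the highest interferon-response mean (3.38 against 2.98), replicate 3 the lowest Dot1l (4.50 against 4.96) and replicate 5 the lowest Hba-a1 (4.57 against 6.64). Among TN-783 libraries, replicate 4 stood apart in the means of inflammasome genes (4.51 against 4.12) and homeostatic microglia genes (4.40 against 4.10), in Slc2a1 (7.10 against 6.50) and on the second component (-11.5 against -3.10). Hbb-bs was highest in TN-783 replicate 1 (9.86 against 9.26) and Il18 lowest in replicate 6 (4.69 against 5.07). The largest totals were 3695650 counts in lean replicate 2 and 3589650 in TN-783 replicate 6.

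Pituitary hormone transcripts were abundant in vehicle replicates 2 and 4: Prl at 1773 and 1273 CPM, Gh at 1049 and 1026, Cga at 797 and 879 and Pomc at 6939 and 3275, where the other 16 libraries reached at most 156 CPM for Pomc. Carry-over of pituitary tissue in the dissection is a candidate explanation: of 6 further pituitary genes, 6 (Tshb, Lhb, Fshb, Pou1f1, Tbx19, Pitx1) were higher in both libraries than in each of the other 16, with Tshb at 179 and 201 CPM against at most 9.73. A change of the vehicle group as a whole was tested without the 2 libraries, where the median log2 difference from lean of Prl, Gh, Cga and Pomc was -0.83. With them it was 5.99, and the largest standard error without them was 1.36. Those 2 libraries were left out for their high values, so a smaller difference without them was to be expected. Prl in the other 4 vehicle libraries lay at 1.39 to 11.5 CPM, which argues against an increase of the size seen with all libraries as a change of the whole group.

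Leaving out lean replicate 6 raised the genes called in vehicle versus lean from 1 to 346; that omission was 1 of 18 planned ones, and the larger count is not offered as a finding. A mislabelled library may be involved: on a line from the other lean libraries (0) to the DIO libraries (1), over 200 genes ranked on the other 17, it lay at 1.39, with other lean libraries at 0.0241 to 0.325 and DIO libraries at 0.256 to 1.30. The DIO libraries lowest and highest on the first component, vehicle replicates 6 (-32.6) and 5 (21.6), lay at 1.22 and 0.256. The RNA integrity score of lean replicate 6 was 10.0, above the other lean libraries (9.4 to 9.7) and the DIO ones (9.5 to 9.9). With RNA integrity as a covariate, all 18 libraries gave 1 called gene (edgeR, 767 at an unadjusted p under 0.05, against 1287 without it). Lean replicate 6 lay at -30.8 on the first component, which followed RNA integrity, so its position cannot tell a wrong label from that axis. Against a wrong label, its Sgk1 (40.1 CPM) lay within the other lean libraries (11.5 to 42.0) and below the DIO ones (46.2 to 113.0), and its haemoglobin share (0.0455%) was in the lean range, which met a bound set against a wrong label. That bound was not used, because vehicle replicate 5 had a share of 0.0320% and Sgk1 is a single gene in a single library, so the label stays open. An RNA composition axis is the other candidate. With the mean of the ribosomal protein list as a covariate, all 18 libraries gave 0 called genes (edgeR, 789 at an unadjusted p under 0.05). That count met the bound set against the axis. Over the 346 genes the covariate lowered the median log2 difference, signed by direction, from 0.44 to 0.20 as well as the median SE, from 0.17 to 0.12. These genes were picked from the same data for their difference, and the covariate itself differed between vehicle and lean by 0.29. Their lowering can therefore arise with or without the axis and does not show the bound to be wrong. A covariate that takes up group difference can end calls, so the count of 0 cannot decide for or against the axis. In the ribosomal covariate fit Sgk1 was at 1.70 (SE 0.31, edgeR adjusted p = 0.135), against 1.75 (SE 0.26) with all 18 libraries and no covariate. Whether the genes called without that library lie along the RNA composition axis stays open too, since the list mean differed between vehicle and lean by 0.29 with all 6 lean libraries (two-sided exact permutation p = 0.156) and by 0.45 without replicate 6 (exact permutation p = 0.00866): with it left out and the covariate added, 0 genes were called (687 at an unadjusted p under 0.05), the median difference went from 0.58 to 0.23 (median SE 0.14 and 0.15), and Sgk1 went from 1.91 (SE 0.27) to 2.09 (SE 0.39, edgeR adjusted p = 0.208), its call ending with a larger SE and no smaller fold.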

How the results depend on the processing

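Fits without the 2 pituitary-bearing vehicle libraries and with the ribosomal covariate were chosen after seeing the data; the others were planned. Where no cause is named below, the cause was not tested. In vehicle versus lean, called genes numbered 22 with DESeq2, 126 with no expression filter, 146 with limma voom and sample weights (141 of them among the 346 called without lean replicate 6), and 0 with at least 1 CPM in 6 libraries, with only the 2 groups compared, with 1 surrogate variable, without the 2 pituitary-bearing libraries, and with the ribosomal covariate with or without lean replicate 6 (edgeR, 789 and 687 at an unadjusted p under 0.05 for the last pair). Leaving out single libraries gave 0 to 346. In TN-783 versus vehicle the count was 6 with no expression filter and 0 in every other fit, leave-one-out fits included. In TN-783 versus lean it was 10 with DESeq2, 27 with no filter, 5 with only the 2 groups, 2 with RIN as a covariate, 4 with voom, and 0 to 5 without single libraries. Called lists in vehicle versus lean fell from 13 to 0 with an estimated correlation, 3 with fry and 7 with the ribosomal covariate, which ended 8 calls and added ependymal and fibroblast genes as lower (adjusted p = 0.0171 and 0.0263). In TN-783 versus vehicle they numbered 3 with RLE scaling, 1 with RIN, 2 (antigen presentation and blood, higher) without the pituitary-bearing libraries, and 0 to 4 without single libraries; in TN-783 versus lean they were 0 with an estimated correlation and 0 with fry. The share of opposite signs moved from 91.0% to 52.8% with separate vehicle libraries against lean and TN-783, which removes the shared libraries. It was 97.0% without the pituitary-bearing ones. Both comparisons still share vehicle libraries there and no unchanged groups were simulated for that setting, so the value cannot be read as reversal. The inflammasome mean turned from -0.003 to 0.0126 in TN-783 versus vehicle with a prior count of 0.5, to 0.00606 as a median and to 0.0529 without the pituitary-bearing libraries. Medians also turned the NF-kB mean in TN-783 versus lean (-0.0756), homeostatic microglia in vehicle versus lean (-0.0276), disease-associated microglia in TN-783 versus lean (0.184) and interferon response in vehicle versus lean (0.0707) and TN-783 versus vehicle (-0.111). Pomc turned to -0.67 and 1.41 without the pituitary-bearing libraries. Aif1 in vehicle versus lean was 0.0313 with the replicate block, 0.113 without the pituitary-bearing libraries and -0.158 to 0.449 without single libraries, and Gfap ranged from -0.0462 to 0.135 in TN-783 versus vehicle and -0.257 to 0.0291 in TN-783 versus lean. Values of rule-named genes were counted under DESeq2, RLE scaling, the replicate block, RIN, 1 surrogate variable and without the pituitary-bearing libraries. The leave-one-out fits with the lowest and highest value of each gene were counted too. Of these values, 565 kept direction and side of the threshold, 18 came to pass it, 2 no longer passed and 7 reversed. Other filters, voom, the ribosomal covariate and the remaining leave-one-out fits are outside these counts. Sgk1 in vehicle versus lean was called in 10 of 18 leave-one-out fits. Same-numbered deviations correlated at -0.125 to 0.385, -0.292 to -0.0411 and -0.400 to 0.0916, with 2, 0 and 0 of 6 best with their own number. These values show no clear pairing of the animals by replicate number and cannot exclude one. The replicate block called 1, 0 and 1 genes. At the depth of these libraries, Nlrp3, Il1b, Casp1, Pycard and Gsdmd lay below the filter.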

Other observations

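The fits with both DIO groups pooled, with the ribosomal covariate, without the 2 pituitary-bearing vehicle libraries, and without lean replicate 6 in the pooled comparison were added after the data were seen, and the genes in the next paragraph were chosen after their values were seen; the other tests here were set before their results.

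In the list of disease-associated microglia, Spp1, which encodes osteopontin, was at a log2 difference of 1.14 (SE 0.46, edgeR adjusted p = 0.401) in vehicle versus lean and -1.53 (SE 0.49, adjusted p = 1.00) in TN-783 versus vehicle. Lpl, the lipoprotein lipase gene, was at 0.94 (SE 0.40, adjusted p = 0.423) and -1.16 (SE 0.42, adjusted p = 1.00). Without the 2 pituitary-bearing vehicle libraries, Spp1 was at -0.14 (SE 0.29) and -0.25 (SE 0.31) and Lpl at -0.18 (SE 0.31) and -0.04 (SE 0.32), so both differences rested on those libraries. The mean of the list was 5.51 and 5.47 in them and 5.11 to 5.33 in the other 4 vehicle libraries. Igf1 was at -0.09 (SE 0.21) and -0.70 (SE 0.23), and at 0.02 (SE 0.23) and -0.82 (SE 0.25, adjusted p = 1.00) without the 2 libraries. Pmch differed by 0.66 in vehicle and 0.42 in TN-783 mice against lean.

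With the 12 DIO libraries pooled against 6 lean ones, Sgk1 was the 1 gene called (1.58, SE 0.24, adjusted p = 0.0347). The next smallest p values belonged to Col1a1 (-1.36, SE 0.25, adjusted p = 0.0645) and Cables1 (0.73, SE 0.14, adjusted p = 0.0645). The pooled count was 758 without lean replicate 6, 5 without the 2 pituitary-bearing libraries, 3 with the ribosomal covariate and 0 with 1 surrogate variable (edgeR, 865 genes at an unadjusted p under 0.05).

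The glucocorticoid-response list was higher in both DIO groups than in lean by camera's preset test, and not with an estimated correlation (adjusted p = 0.221 for vehicle and 0.390 for TN-783; 0.310 and 0.381 with the ribosomal covariate). With the ribosomal covariate the list median in vehicle versus lean was 0.46 against 0.55 without it, above the bound set against an RNA composition axis, but the jackknife SE was 0.27, a criterion tightened after the value was seen, so part of the difference may still follow that axis. In TN-783 versus lean the median was 0.38 with the covariate and 0.39 without it, and no jackknife SE was computed. Under the covariate 10 and 11 of 11 genes were higher in vehicle and TN-783, and camera's preset test still called the list (adjusted p = 3.99e-07 and 1.81e-06). Blood left in the tissue could contribute: deviations from the group means of the list and of the log2 haemoglobin share correlated at r = 0.183 (permutation p = 0.381; rho 0.220, permutation p = 0.371; 0.205 without the 2 farthest libraries; 1 relation) over 18 libraries, with an upper 95% bound of 0.622, which leaves it open. Repeated oral gavage rather than diet could not be tested, since 0 lean libraries came from mice dosed during treatment; diet and dosing cannot be told apart.

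Other splits of the 12 libraries of each comparison into 6 and 6 were tested, 100 per comparison with the real one. For vehicle versus lean, 2 splits, the real one included, gave as many called lists as the real 13 (highest other 13). The other of these splits only exchanged vehicle replicate 6 and lean replicate 6. Taken alone, that share of splits is under 0.05, but several counts were tested this way without adjustment. Chance is therefore not excluded for that count, and camera's preset test called a median of 4 lists in the other splits. Nor was chance excluded for the 1 called gene of vehicle versus lean (7 splits, highest other 1212) or its 1287 genes at an unadjusted p under 0.05 (12 splits, highest other 3282). The splits with 1212 and 1051 genes joined lean replicate 6 and 1 other lean library with vehicle replicates 1, 2, 3 and 6, which points to a structure of the samples. Lean replicate 6 and these vehicle libraries lay at -32.6 to -2.47 on the first component (RNA integrity 9.7 to 10.0). Vehicle replicates 4 and 5 lay at 14.9 and 21.6 (9.5 and 9.6). Against that pattern, the other lean library, replicate 5 or 3, lay at 20.4 or 22.2 (9.6 or 9.4), and lean replicate 4, not joined, also had a score of 9.7. For TN-783 versus vehicle, chance was not excluded for the 309 unadjusted genes (80 splits, highest other 2127), nor for TN-783 versus lean for the 966 unadjusted genes (13 splits, 3233) or the 9 lists (6 splits, 10). A real count of 0 is reached by all 100 splits whatever the data, so the splits decide nothing for the 0 genes (highest other 0) and 0 lists (13) of TN-783 versus vehicle and the 0 genes (1215) of TN-783 versus lean; at an unadjusted p under 0.05 edgeR gave 309 and 966 genes there, and DESeq2 called 0 and 10.

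Malat1, a nuclear RNA, was at 1082 CPM in lean, 721 in vehicle and 706 in TN-783 libraries (two-sided exact permutation p = 0.0130 and 0.00433 against lean, 0.182 and 0.0909 adjusted over 42 tests). In edgeR its adjusted p was 0.242 in vehicle and 0.421 in TN-783 against lean. It was called as lower with no expression filter (0.000285 and 0.000325), and in vehicle versus lean with voom (0.0269) and without lean replicate 6 (0.0415). In lean, vehicle and TN-783 libraries the lowest Malat1 (885, 518 and 564 CPM) was in the library lowest on the first component (-30.8, -32.6 and -25.3). Vehicle replicate 1, at -2.47, also had 518 CPM. Its relation to that component was not tested, so the group difference may follow it in part.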
